A study of Homo sapiens with 12 samples.

How the data were processed

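RNA was measured by sequencing in 12 libraries of WS1, an established line of human skin fibroblasts, grown in DMEM with 10% FBS and collected 48 h after transfection, per the labels. The libraries fall into 4 groups of 3: an interference vector against AUF1 (sh_AUF), its control vector (sh_NC), an overexpression vector for AUF1 (OE_AUF) and its control vector (OE_NC). Groups and replicate numbers were taken from the sample titles. For a pair of the sh_AUF libraries, the treatment label names AUF2 or AUF3 in place of AUF1; titles and source names put both in sh_AUF, where they were kept. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

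The authors deposited 1 table of FPKM values (reads scaled by gene length and by a library total) for all 12 libraries, with gene lengths, coordinates, biotypes and names. HISAT2 2.0.5 and DESeq2 1.16.1 are named in the submitters' processing notes without their roles; the read counter, genome build and annotation are not given in the sources used here. The table has 58735 Ensembl genes, and the coordinates of all 58735 equal those of GENCODE release 29, so positions are given on GRCh38. A further 237 entries without an Ensembl ID were kept in the tests where they passed the filter (170 did) and are not named. Whether reads were assigned by strand is not stated, so values of antisense genes, and of genes that overlap others, are uncertain. The same holds for genes with near-identical copies, such as HLA-DRB1, HLA-DRB5, the histone genes and the ribosomal protein genes.

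Multiplied by gene length, the FPKM values of each library came in whole multiples of 1 step, so reads per gene could be recovered (100% of values whole, within 0.01 read). The libraries held 18062172 to 25673595 recovered reads. A single read in a gene of 1 kb was worth 0.038 to 0.062 FPKM, and the 3 reads that a count of 0 allows were worth 0.114 to 0.186 FPKM; this floor covers counting error only. The library total implied by the step was not the sum of the recovered reads. Recovered reads divided by that total ranged from 0.92 to 0.945 in the AUF1-vector libraries (sh_AUF and OE_AUF), from 1.03 to 1.04 in 5 of the control libraries, and reached 1.22 in OE_NC replicate 3. The recovered reads were used for depth, for 1 alternative scaling and to compare libraries by counting noise (chi-square per gene with at least 20 summed reads). No pair of libraries differed by less than counting noise alone, so none were merged.

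Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested: 13942 genes, of which 11091 were protein-coding. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with no further scaling, 4 group means, 8 residual degrees of freedom and empirical Bayes moderation with a trended, robust prior. Fold changes are on this scale, which understates the changes of low genes. SEs and p-values use 1 spread per gene shared by all 4 groups, OE_NC replicate 3 included. They are thus not the spread of the groups compared alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The comparisons were sh_AUF minus sh_NC, OE_AUF minus OE_NC, the difference between these changes, and OE_NC minus sh_NC. OE_AUF minus sh_AUF was added after the data were seen. HNRNPD, the gene of AUF1, was also compared by exact two-sided permutation of 3 against 3 libraries, for which 0.1 is the smallest possible p.

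Gene lists, 38 in all, were tested against the other genes with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over lists. The same test with an estimated correlation, and counts of called members over all genes and adjusted over the list alone, are given beside it. Some lists share members, such as COL1A1, COL1A2 and COL3A1 in collagens and fibroblast identity, so their tests are not independent. The lists cover AUF1 targets, RNA binding, decay and splicing, inflammation and interferon, cell cycle, p53, apoptosis and senescence, matrix and myofibroblast genes, stress responses, metabolism, growth factors, the clock, protein turnover, ribosome and mitochondria, histones, long noncoding RNAs, fibroblast identity and markers of 6 other cell types.

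Named genes were picked by rule. For each vector comparison these were the 10 protein-coding genes with the largest change per direction, among called genes with mean FPKM of at least 5 over the 6 libraries and no overlap between groups. Up to 4 called members per list past its test were added, as were the 5 largest per sign pattern among genes called in both vector comparisons and the 5 largest per direction of the other comparisons. HNRNPD, HNRNPDL, HNRNPAB, MYC, CCND1, CDKN1A, IL6 and CXCL8 were reported whatever their result. Sex-linked marker genes were left out. The groups, the fit, the lists and the rule, and most alternatives, were fixed before the data were examined.

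Alternatives were a pseudocount of 0.1, no filter, a filter at mean FPKM of 5, rescaling by median ratio or to a common sum (TPM), the 6 libraries of a comparison alone, a constant prior, protein-coding genes only, a replicate block and each library left out in turn. Scaling by recovered reads, an adjustment for gene length and the lists without OE_NC replicate 3 were added after the data were seen. The scripts were tested on simulated data with 200 changed genes in the sh_AUF comparison. The simulated reads had a dispersion of 0.002 and library totals set from the summed reads. They thus do not test the scaling, nor changes in as many genes as were called here. With no library standing apart (12714 genes), 25.8%, 95.2% and 97% of genes changed 1.2, 1.5 and 2 times were recovered, and 7 of 147 calls were false. With OE_NC replicate 3 given its own deviation (12729 genes), 0%, 25.8% and 77.3% were recovered, and 0 of 68 calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.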

Results

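Gene expression was measured in 12 RNA sequencing libraries of WS1, a human skin fibroblast line, 48 h after transfection. The groups were an interference vector against AUF1 (sh_AUF), an overexpression vector for AUF1 (OE_AUF) and the control vector of each (sh_NC and OE_NC), with 3 libraries per group. The series title asks which genes AUF1 affects in skin cells. AUF1 is the protein of HNRNPD and binds AU-rich elements in mRNA. Libraries held 18062172 to 25673595 recovered reads, with 22259149 or more in each of sh_NC and 20565321 or fewer in each of OE_AUF.

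HNRNPD (ENSG00000138668, GRCh38 chromosome 4, 82352498 to 82374503, minus strand) was read first, because it checks the labels. Its FPKM was 53.8, 55 and 53.2 in sh_NC replicates 1, 2 and 3, and 43, 41.2 and 40.6 in those of sh_AUF. In OE_NC it was 53.6, 53.3 and 65.5, and in the libraries labelled OE_AUF it was 38.1, 38.5 and 37.8. Each value rests on 5161 to 9482 reads. HNRNPD was thus 1.29-fold lower in sh_AUF than in sh_NC (log2 change -0.37, SE 0.08, limma adjusted p = 0.00297, n = 3 per group). In the libraries labelled OE_AUF it was 1.49-fold lower than in OE_NC (-0.57, SE 0.08, adjusted p = 0.000186), which goes against that label. Both differences had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The changes of HNRNPD differed by -0.2 (limma adjusted p = 0.322), and the control groups by 0.08 (adjusted p = 0.515). In sh_AUF its relatives HNRNPDL and HNRNPAB fell by more than HNRNPD, as given below. The fall of HNRNPD alone thus does not show that the interference vector acted on it. With adjustment for gene length, the change of HNRNPD in sh_AUF was -0.23 and not past the threshold (adjusted p = 0.0956; range over the alternatives 2.79e-07 to 0.0956).

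**Figure D1:**
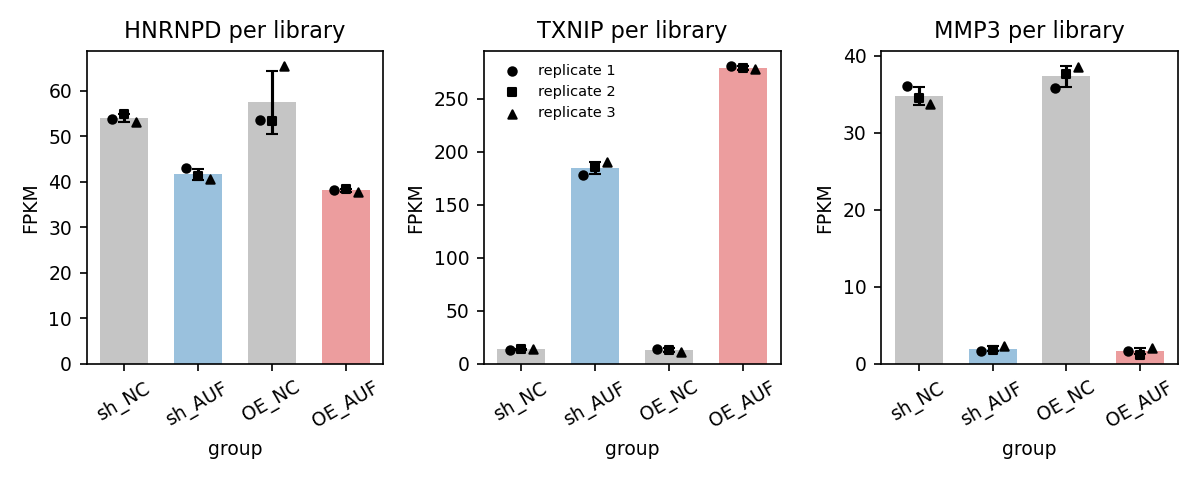
FPKM of HNRNPD, TXNIP and MMP3 (vertical axes, from 0) in each library; bars are group means, error bars the SD of 3 libraries and symbols the replicates. HNRNPD averaged 41.6 in sh_AUF and 38.1 in OE_AUF, below both control groups at 54 and 57.5, while TXNIP rose and MMP3 fell in both AUF1-vector groups.

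The comparison of sh_AUF with sh_NC asks what changed with the interference vector. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an arrestin-family inhibitor of thioredoxin and of glucose uptake, rose 12.5-fold, from 13.9 ± 0.371 to 185 ± 6.04 FPKM (SD, n = 3; log2 change 3.64, SE 0.09, limma adjusted p = 7.93e-09). DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036), a stress-induced inhibitor of mTORC1, rose 8.62-fold, from 4.3 ± 0.487 to 44.6 ± 2.6. MMP3 (ENSG00000149968, chromosome 11, 102835801 to 102843803), the matrix protease stromelysin-1, fell 12.1-fold, from 34.8 ± 1.14 to 1.96 ± 0.348 (-3.6, SE 0.11, adjusted p = 2.5e-08). THBS1 (ENSG00000137801, chromosome 15, 39581079 to 39599466), the matrix glycoprotein thrombospondin-1, fell 7.81-fold, from 94.1 ± 2.41 to 11.2 ± 0.629 (-2.97, SE 0.29, adjusted p = 1.51e-05). The SEs and adjusted p rest on the spread over all 12 libraries, OE_NC replicate 3 included, while each SD is that of 3 libraries.

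Others among the largest increases were PTGES, which makes prostaglandin E2 (6.25-fold), the transcription factor SNAI1 (6.12-fold), the MHC class II genes HLA-DRB1 (6.05-fold) and HLA-DRA (5.85-fold), CHAC1, a glutathione-degrading enzyme induced by stress (5.98-fold), C1QL1 (5.86-fold), and RARRES2, the chemerin gene, and LXN (5.51-fold each). HLA-DRB1 has near-identical copies, so its value is uncertain. The largest decreases after MMP3 and THBS1 were those of TFRC, the transferrin receptor (6.02-fold), ODC1, the first enzyme of polyamine synthesis (5.39-fold), AMIGO2 and FJX1 (5.14-fold each), the tyrosine kinase ABL2 (5.09-fold), PAPPA (4.92-fold), ENC1 (4.81-fold) and INHBA, an activin subunit (4.53-fold). CCND1, cyclin D1, fell 4.08-fold and the transcription factor MYC 1.53-fold, and the cytokines IL6 and CXCL8 fell 1.7-fold and 1.78-fold. HNRNPDL and HNRNPAB, relatives of HNRNPD, fell 1.41-fold and 1.68-fold. CDKN1A, the cell cycle inhibitor p21, had a log2 change of -0.2 (adjusted p = 0.0799), and passed without OE_NC replicate 3 (6.57e-05), with the 6 libraries alone (0.000999), with length adjustment (0.000408) and under TPM (0.0129), in a range from 6.57e-05 to 0.457.

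Of 39 hnRNPs and AU-rich-element-binding proteins tested, 25 fell, 2 rose and 12 did not pass (adjusted over the list alone, 27 and 2; median log2 change -0.39, camera adjusted p = 0.000341, and adjusted p = 0.063 with an estimated correlation). HNRNPM fell 2.82-fold and SYNCRIP 2.33-fold, while ZFP36, which directs the decay of AU-rich mRNAs, rose 2.55-fold. Of 47 genes of mRNA decay, 21 fell, such as the exonuclease XRN2 (1.67-fold) and the deadenylase PARN (1.61-fold), and 3 rose (adjusted over the list alone, 20 and 3; median -0.32, adjusted p = 0.0155, and adjusted p = 0.076 with an estimated correlation). Of 33 splicing regulators 17 fell, SRSF1 by the most (3.07-fold), and 7 rose, the same counts adjusted over the list alone (median -0.3, adjusted p = 0.0497, and adjusted p = 0.12 with an estimated correlation). That call ended without sh_NC replicate 1 (0.0532) or 3 (0.0548), sh_AUF replicate 1 (0.0605) or 3 (0.0657), OE_NC replicate 2 (0.0537) or OE_AUF replicate 1 (0.0542), 2 (0.0526) or 3 (0.0522). Of 21 reported AUF1 targets, 11 fell and 4 rose (adjusted over the list alone, 12 and 5), with a median of -0.48 that did not pass (adjusted p = 0.078).

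Of 43 interferon-stimulated genes, 24 fell, among them HERC6 (3.34-fold), OAS2 (2.61-fold) and MX1 (2.44-fold), and 6 rose, the same counts adjusted over the list alone (median -0.52, adjusted p = 0.00601, and adjusted p = 0.063 with an estimated correlation). Of 29 inflammatory genes, 16 fell, led by the chemokines CXCL5 (3.66-fold) and CXCL1 (3.53-fold), and 8 rose (adjusted over the list alone, 18 and 8; median -0.65, adjusted p = 0.026, and adjusted p = 0.12 with an estimated correlation). Growth factors and receptors fell in 16 of 24 cases and rose in 3, the same counts adjusted over the list alone, with the Wnt inhibitor DKK1 4.25-fold and the BMP inhibitor GREM1 3.56-fold lower (median -0.82, adjusted p = 0.00103, and adjusted p = 0.063 with an estimated correlation). Heat shock genes fell in 16 of 21 cases and rose in 3, with the chaperone HSP90AA1 3.02-fold lower (median -0.6, adjusted p = 0.00103, and adjusted p = 0.15 with an estimated correlation). Of 30 proteasome subunits 17 fell and 0 rose, PSMD2 by 2.55-fold (median -0.53, adjusted p = 0.000147, and adjusted p = 0.5 with an estimated correlation).

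Among cell cycle lists, 23 of 38 mitosis genes fell and 2 rose, with the proliferation marker MKI67 1.95-fold and cyclin B1 (CCNB1) 1.88-fold lower (median -0.41, adjusted p = 0.00601, and adjusted p = 0.11 with an estimated correlation). Replication-dependent histones fell in 7 of 9 cases, HIST1H2AC by 3.55-fold (median -1.23, adjusted p = 0.0073, and adjusted p = 0.35 with an estimated correlation). Upward lists were the circadian clock, with 8 of 15 members higher and 1 lower (adjusted over the list alone, 8 and 2; median 0.48, adjusted p = 0.0104, and adjusted p = 0.11 with an estimated correlation), and long noncoding RNAs, with 12 of 18 higher and 1 lower (median 0.85, adjusted p = 0.00103, and adjusted p = 0.13 with an estimated correlation). PER1, a repressor of the clock, rose 3.6-fold, while CLOCK, its activator, fell 2.25-fold. NEAT1, the scaffold of paraspeckles, rose 5.48-fold and MALAT1 2.22-fold. Of 57 cytosolic ribosomal proteins 1, RPL12, was called (1.63-fold higher; 0 adjusted over the list alone), with a list median of 0.3 (adjusted p = 0.0207, and adjusted p = 0.81 with an estimated correlation); 53 were called higher without OE_NC replicate 3, and the list's call ended without sh_AUF replicate 1 (0.0678). The call of RPL12 ended without any 1 of the 6 libraries compared, with adjusted p from 0.0575 to 0.0876, and without a filter (0.0627), in a range from 4.12e-08 to 0.0876.

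Most lists that did not pass in sh_AUF had members going both ways. ATF4 and amino acid response genes, 33 in all, rose in 16 cases and fell in 11 (median 0.29, adjusted p = 0.237), and 27 immediate early genes in 12 and 9 (0.19, 0.286). Matrix proteases and inhibitors rose in 8 and fell in 13 of 25 cases (-0.43, adjusted p = 0.286), and myofibroblast genes in 4 and 12 of 26 (-0.27, 0.103). Collagens and matrix glycoproteins rose in 10 and fell in 9 of 36 cases, with a median of 0.05, a mean of -0.06 and an upward test (adjusted p = 0.34). Counts of higher and lower members were 6 and 21 for DNA replication (adjusted p = 0.0921), 5 and 10 for p53 targets (0.32), 6 and 14 for apoptosis (0.247), 6 and 12 for senescence (0.134), 4 and 7 for NRF2 targets (0.68), and 8 and 5 for cholesterol synthesis (0.458). They were 8 and 9 for glycolysis (0.792), 7 and 12 for autophagy (0.588), 1 and 5 for nuclear-encoded oxidative phosphorylation (0.815), 4 and 3 for fibroblast identity (0.815), and 8 and 8 for ER chaperones (0.809), whose median of -0.06 went against an upward test. Fatty acid genes (2 and 9, adjusted p = 0.118) and mitochondrially encoded mRNAs (3 and 0, adjusted p = 0.129) passed without OE_NC replicate 3, at 0.0198 and 0.0299, but not with an estimated correlation as well (adjusted p = 0.3 and 0.55). Counts of oxidative phosphorylation genes became 21 and 12 without that library. Adjusted over the list alone, these counts became 18 and 11 for ATF4 genes, 6 and 22 for DNA replication, 6 and 15 for apoptosis, 6 and 13 for senescence, 4 and 6 for NRF2 targets, 0 and 2 for oxidative phosphorylation and 1 and 0 for mitochondrially encoded mRNAs, and stayed the same elsewhere.

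By limma, 7758 of 13942 genes were called between sh_AUF and sh_NC, 3578 higher and 4180 lower, and 1402 of them changed at least 2-fold. With the 6 libraries of this comparison alone, 10581 were called. The groups did not overlap for 10969 genes (78.7%, against 10% by chance). Called genes were higher in 46.1% of cases, against 61.7% when scaled by recovered reads, and each of the 13 lists past the threshold kept its direction under all scalings. None of these 13 calls held with an estimated correlation, though hnRNPs passed with OE_NC replicate 3 also left out (0.036). Where no count adjusted over the list alone is given for a list, in either vector comparison, it was the same.

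**Figure D2:**
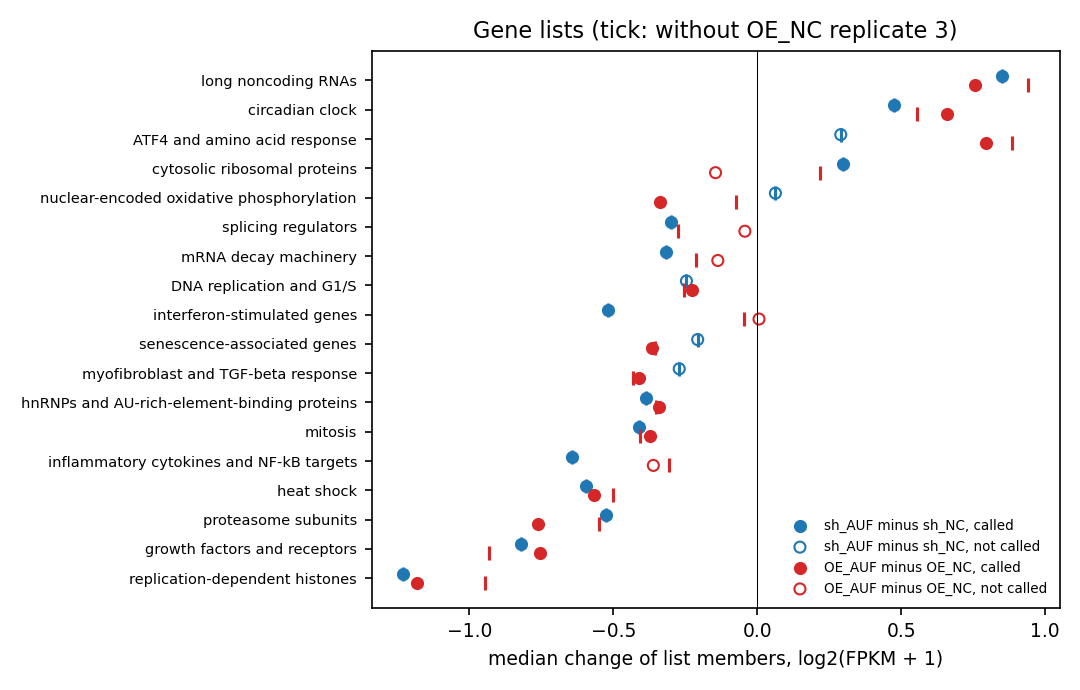
Median log2 change of list members (horizontal axis, log2 of FPKM + 1) for lists called in either vector comparison; filled circles passed camera's test, open circles did not, and ticks give the median without OE_NC replicate 3. Proteasome subunits lay at -0.53 for sh_AUF and -0.76 for OE_AUF; ribosomal proteins lay at -0.15 for OE_AUF and at 0.22 without that library.

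The comparison of OE_AUF with OE_NC asks what changed with the overexpression vector; its directions come from libraries labelled OE_AUF in which HNRNPD was lower. TXNIP was 20.4-fold higher, at 279 ± 1.83 against 12.8 ± 1.74 FPKM (SD, n = 3; log2 change 4.35, SE 0.09, limma adjusted p = 1.3e-09), and DDIT4 13.8-fold, at 72.9 ± 1.76 against 4.36 ± 0.105. CHAC1 was 10.5-fold higher and ASNS, asparagine synthetase, 4.4-fold. MMP3 was 14.7-fold lower (-3.87, SE 0.11, adjusted p = 1.79e-08), and DKK1, at 21.7 ± 0.128 against 168 ± 8.26 FPKM, 7.43-fold (-2.89, SE 0.06, adjusted p = 1.68e-09).

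Further increases in the libraries labelled OE_AUF were those of TSC22D3, a glucocorticoid-induced transcriptional regulator (6.15-fold), PTGES (5.38-fold), HLA-DRA (5.33-fold), ICAM5 (4.62-fold), CDC42EP5 (4.34-fold), the arrestin-domain gene ARRDC3 (4.33-fold) and C1QL4 (4.28-fold). FJX1 (7.22-fold), THBS1 (6.5-fold), TFRC (6.15-fold), PPP1R10 (5.4-fold), the transcription factor ATF5 (4.91-fold), EMP3 (4.85-fold), HIST1H2BK (4.7-fold) and AMIGO2 (4.51-fold) were lower. CCND1 was 2.67-fold, MYC 1.88-fold, IL6 1.76-fold and CDKN1A 1.38-fold lower. HNRNPAB and HNRNPDL were 2.06-fold and 1.41-fold lower. CXCL8 was 1.29-fold lower (adjusted p = 0.00501), a call lost under TPM (0.57), recovered-read scaling (0.41), gene length adjustment (0.153) and the 6 libraries alone (0.0911), within a range from 3.97e-08 to 0.57.

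ATF4 and amino acid response genes were higher in 25 of 33 cases and lower in 3 (adjusted over the list alone, 26 and 3; median 0.8, camera adjusted p = 3.35e-09; 0.046 with an estimated correlation). The circadian clock had 11 of 15 members higher and 1 lower (median 0.66, adjusted p = 0.000135; 0.046 with an estimated correlation, lost at 0.079 without OE_NC replicate 3), with PER1 4.13-fold and NR1D1, a nuclear receptor of the clock, 2.48-fold higher. Long noncoding RNAs were higher in 11 of 18 cases and lower in 1, DANCR (median 0.76, adjusted p = 0.000349, and adjusted p = 0.11 with an estimated correlation), with NEAT1 5.53-fold and MALAT1 3.17-fold higher.

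Lower in the libraries labelled OE_AUF were 28 of 30 proteasome subunits, PSMD2 by 2.4-fold (median -0.76, adjusted p = 1.75e-08, and adjusted p = 0.3 with an estimated correlation), 14 of 21 heat shock genes (-0.57, 0.000135, and adjusted p = 0.13 with an estimated correlation) and 8 of 9 histones (-1.18, 0.00038, and adjusted p = 0.2 with an estimated correlation). HSP90AA1 was 2.96-fold lower. Growth factors and receptors were lower in 16 of 24 cases and higher in 3 (adjusted over the list alone, 17 and 4; median -0.76, adjusted p = 0.000788, and adjusted p = 0.053 with an estimated correlation), WNT5B by 4.22-fold. Among hnRNPs and AU-rich-element-binding proteins 24 of 39 were lower and 5 higher (median -0.34, adjusted p = 0.000868, and adjusted p = 0.053 with an estimated correlation), with HNRNPM 3.44-fold lower and ZFP36 2.14-fold higher. Myofibroblast genes were lower in 13 of 26 cases and higher in 3 (median -0.41, adjusted p = 0.00658, and adjusted p = 0.054 with an estimated correlation), among them TAGLN (2.99-fold) and TPM1 (2.5-fold), which bind actin. Mitosis genes were lower in 19 of 38 cases and higher in 3 (-0.37, adjusted p = 0.0138, and adjusted p = 0.11 with an estimated correlation).

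The remaining lists depended on OE_NC replicate 3. Calls of DNA replication genes (17 of 41 lower and 4 higher, median -0.23, adjusted p = 0.0367, and adjusted p = 0.11 with an estimated correlation), senescence genes (14 of 25 lower and 4 higher, -0.37, 0.026, and adjusted p = 0.3 with an estimated correlation) and oxidative phosphorylation genes (12 of 46 lower and 1 higher; 8 and 1 adjusted over the list alone; -0.34, 0.0204, and adjusted p = 0.75 with an estimated correlation) ended without it, at 0.0902, 0.11 and 0.416. The median of DNA replication genes was 0.001 under TPM and 0.004 by recovered reads, and -0.17 and -0.14 relative to all genes. Against the downward direction of their lists, CDT1, which licenses replication origins, was 2.42-fold higher, as were the senescence-list members IL1A, a cytokine (2.52-fold), and GDF15, a stress-induced growth factor (2.21-fold). Ribosomal proteins (0 of 57 called, median -0.15, adjusted p = 0.467) turned upward without that library, with 42 higher and a median of 0.22 (1.04e-05, and adjusted p = 0.53 with an estimated correlation). Fatty acid genes (3 higher and 6 lower of 20, adjusted p = 0.35) passed downward without it (0.0203, and adjusted p = 0.31 with an estimated correlation).

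Lists that did not pass in OE_AUF, with higher and lower members, were AUF1 targets (4 and 12 of 21, median -0.37, adjusted p = 0.112), mRNA decay (4 and 18, 0.124), splicing (5 and 13, 0.198), inflammatory genes (8 and 17, 0.198), p53 targets (6 and 9, 0.411) and apoptosis (8 and 11, 0.41). Interferon-stimulated genes were higher in 10 and lower in 13 cases, with a median of 0.006, a mean of -0.03 and a downward test (adjusted p = 0.875). Cholesterol synthesis (4 and 7) had a median of 0.06, a mean of -0.09 and a downward test (0.875), and ER chaperones (8 and 6) a median of -0.06 and an upward test (0.771). The others were collagens (9 and 10, 0.975), matrix proteases (5 and 12, 0.0757), NRF2 targets (3 and 5, 0.42), glycolysis (6 and 15, 0.192), immediate early genes (13 and 10, 0.284), autophagy (6 and 11, 0.235), mitochondrially encoded mRNAs (1 and 6, 0.32) and fibroblast identity (1 and 6, 0.192). Adjusted over the list alone, counts became 5 and 12 for AUF1 targets, 4 and 17 for mRNA decay, 6 and 10 for p53 targets, 8 and 12 for apoptosis and 1 and 7 for fibroblast identity, and stayed the same elsewhere.

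In all, 7175 genes were called between OE_AUF and OE_NC by limma, 3376 higher and 3799 lower in the libraries labelled OE_AUF, and 1144 changed at least 2-fold. With the 6 libraries of this comparison alone, 4729 were called, so the counts of the 2 vector comparisons do not rank their responses. The groups did not overlap for 7741 genes (55.5%, against 10% by chance). Called genes were higher in 47.1% of cases, but in 66.4% under TPM and 67.6% by recovered reads. The median of all genes moved from -0.04 to 0.17 and 0.15 under those scalings; relative to it all 13 called lists kept their direction. With an estimated correlation and without OE_NC replicate 3, hnRNPs and growth factors passed (0.032 each) beside ATF4 genes (0.032). OE_NC replicate 3 stood apart from the other control libraries and is described with the controls.

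Genes called in both vector comparisons mostly moved the same way. The comparisons share no library, but a single fit estimated each gene's spread over all 12 libraries. The calls are thus linked, and the counts for independent lists serve only as a reference. Higher in both were 2586 genes (866 for independent lists) and lower in both 2837 (1139), including TXNIP, DDIT4, CHAC1 and PTGES, and MMP3, THBS1, FJX1, TFRC and DKK1. AC254633.1, a gene without a settled function, was 5.92-fold and 6.98-fold higher. Opposite calls numbered 33, with 23 lower in sh_AUF and higher in the libraries labelled OE_AUF (1012 for independent lists) and 10 the other way (975). Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.807 and Spearman's rho of 0.775.

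The amino acid transporter SLC7A5 (ENSG00000103257, chromosome 16, 87830023 to 87869488) was 1.7-fold lower in sh_AUF and 1.52-fold higher in OE_AUF. OAS1, an interferon-induced antiviral enzyme, was 1.43-fold lower and 1.33-fold higher, and the stanniocalcin gene STC2 1.61-fold lower and, with a log2 change of 0.22, higher. The OE_AUF call of STC2 ended with the 6 libraries alone (0.136, in a range from 0.000202 to 0.136). PSAT1, an enzyme of serine synthesis, was 1.21-fold lower and 1.95-fold higher. Its lower call ended under TPM (0.0801) and recovered-read scaling (0.213), in a range from 1.15e-06 to 0.213. HELZ2, the last gene named by rule for this pattern, lost each call under some alternative. Its limma adjusted p reached 0.306 in sh_AUF and 0.116 in OE_AUF. Of the other pattern, TRIB2, SPARC, CXCL6, B4GAT1 and NFS1 were named by rule. All lost their OE_AUF call under TPM, at 0.76, 0.251, 0.269, 0.996 and 0.779, the highest values of their ranges. The sh_AUF call was also lost under some alternative for TRIB2, SPARC, CXCL6 and NFS1. Their limma adjusted p there reached 0.117, 0.162, 0.42 and 0.186, while that of B4GAT1 stayed at 0.044 or below. The count of opposite calls was 168 without OE_NC replicate 3, 20, 21 and 17 without sh_NC replicates 1, 2 and 3, 19 and 20 without sh_AUF replicates 1 and 3, and 18 and 16 without OE_AUF replicates 2 and 3. Same-direction calls rose to 8940 without OE_NC replicate 3.

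**Figure D3:**
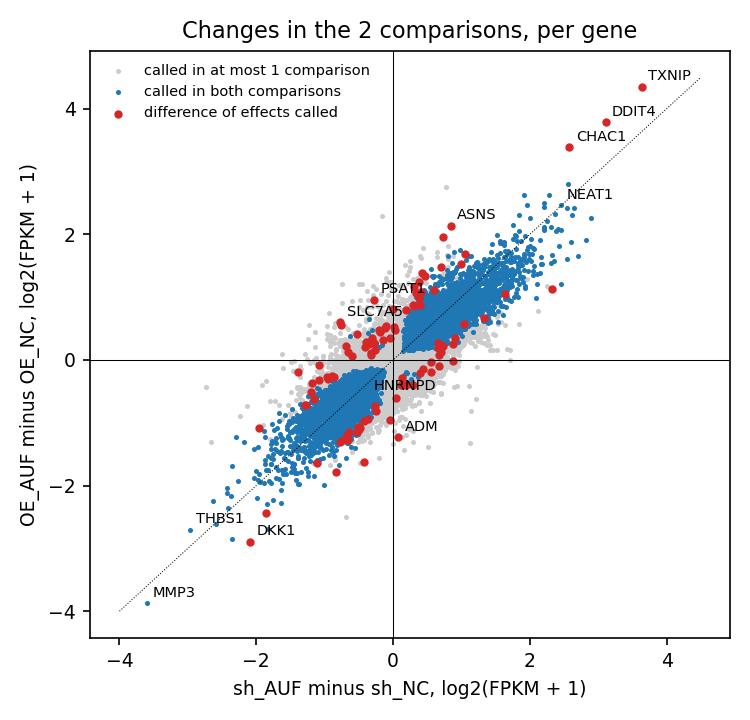
Log2 change of each of 13942 genes in sh_AUF (horizontal axis) and OE_AUF (vertical axis), on log2 of FPKM + 1; blue points were called in both comparisons, red points had changes that differed, and the dotted line marks equal change. Most points lie along that line (r = 0.807), with 5423 genes called the same way in both and 33 in opposite ways.

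The difference between the vector responses asks where they parted; directions again rest on libraries labelled OE_AUF in which HNRNPD was lower. The change of SLC7A5 was 1.37 log2 units higher in OE_AUF than in sh_AUF (SE 0.08, limma adjusted p = 0.000102), that of PSAT1 1.24 (SE 0.09, 0.000196) and that of AARS, the alanyl-tRNA synthetase, 0.95 (0.000929). MEST lay 1.2 units lower, at -1.2 (SE 0.08, adjusted p = 0.000102). DKK1 lay at -0.81 (0.00388), a call lost under TPM (0.124, in a range from 3.98e-06 to 0.124). In all, 100 genes were called, 59 with a higher and 41 with a lower change in OE_AUF. Under TPM 79 genes were called, 73.4% of them higher against 59% of the 100, and the median difference of all genes moved to 0.22.

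ATF4 and amino acid response genes had higher changes in OE_AUF in 21 of 33 cases and lower in 0 (adjusted over the list alone, 25 and 0; median difference 0.69, camera adjusted p = 3.81e-24; 0.0016 with an estimated correlation). Interferon-stimulated genes differed the same way in 8 of 43 cases (adjusted over the list alone, 23; median 0.44, adjusted p = 4.9e-10; 0.0015 with an estimated correlation), and inflammatory genes in 2 of 29 (adjusted over the list alone, 11, with 1 lower; 0.31, adjusted p = 0.00038; 0.044 with an estimated correlation). The number of genes called rose to 2738 without OE_NC replicate 3, which held all 100, and was 54 without OE_NC replicate 2, 25, 28 and 19 without sh_NC replicates 1, 2 and 3, 26, 30 and 28 without those of sh_AUF, and 22, 30 and 20 without those of OE_AUF.

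**Figure D4:**
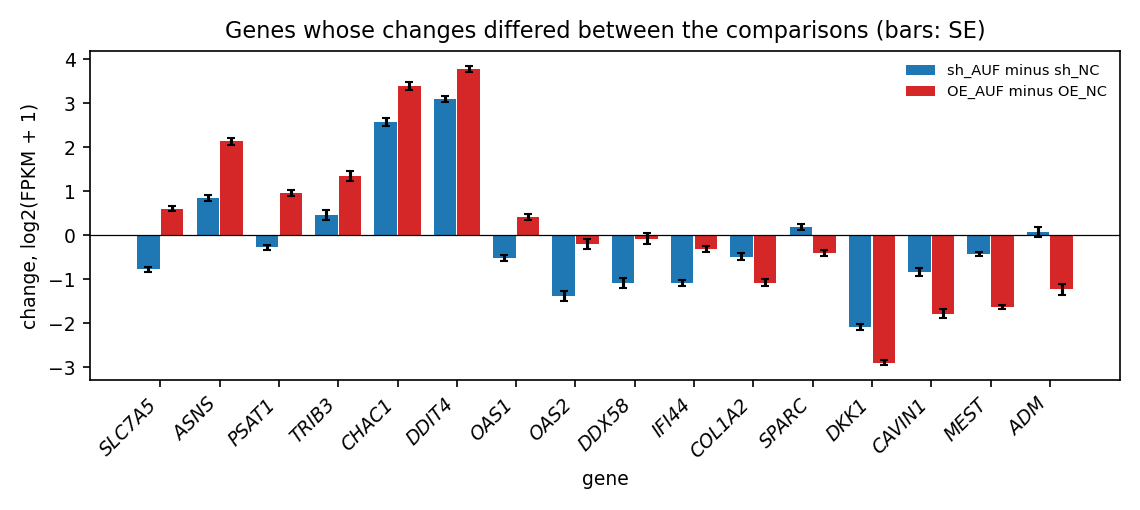
Log2 changes of 16 genes in sh_AUF (blue) and OE_AUF (red), each against its own control group, on log2 of FPKM + 1; error bars are standard errors. SLC7A5 was lower in sh_AUF (-0.77) and higher in OE_AUF (0.6), while MEST was lower in both, at -0.43 and -1.63.

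Set against each other directly, a comparison added after the data were seen, the libraries labelled OE_AUF had 23 of 33 ATF4 and amino acid response genes higher than sh_AUF and 0 lower (adjusted over the list alone, 28 and 0; median 0.74, camera adjusted p = 8.73e-40; 0.00025 with an estimated correlation). SLC7A5 was 2.51-fold higher (1.33, SE 0.06, adjusted p = 5.27e-06), PSAT1 2.35-fold, ASNS 2.26-fold, TRIB3, a stress-induced pseudokinase, 2.08-fold and CHAC1 1.99-fold. Interferon-stimulated genes were higher in 16 of 43 cases and lower in 0 (adjusted over the list alone, 25 and 0; median 0.42, adjusted p = 2.18e-18; 0.00016 with an estimated correlation), with OAS2 2.02-fold, OAS1 1.98-fold, the RNA sensor DDX58 1.82-fold and IFI44 1.78-fold higher. Inflammatory genes were higher in 9 of 29 cases and lower in 1 (adjusted over the list alone, 13 and 1; 0.27, adjusted p = 2.09e-07; 0.0053 with an estimated correlation), with the pentraxin PTX3 1.74-fold and the cytokine IL1B 1.64-fold higher.

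Lower in the libraries labelled OE_AUF than in sh_AUF were 8 of 36 collagens and matrix glycoproteins (adjusted over the list alone, 11; median -0.2, adjusted p = 1.7e-07, and adjusted p = 0.11 with an estimated correlation), with SPARC 1.46-fold lower. MEST was 2.21-fold, ADM, the vasodilator adrenomedullin (ENSG00000148926, chromosome 11, 10304680 to 10307397), 2.11-fold and the caveolar gene CAVIN1 1.81-fold lower. Fibroblast identity genes were lower in 4 of 13 cases (-0.2, adjusted p = 3.07e-05, and 0.0096 with an estimated correlation). That list shares COL1A1, COL1A2 and COL3A1 with the collagens, so its test partly repeats theirs. Glycolysis genes were lower in 5 of 33 cases (adjusted over the list alone, 7, median -0.12, adjusted p = 4.85e-06, and 0.041 with an estimated correlation). Myofibroblast genes were lower in 3 of 26, with CTGF 1.52-fold lower (adjusted over the list alone, 7, with 1 higher, -0.12, 0.000723, and 0.017 with an estimated correlation). Cholesterol genes were lower in 2 of 25 (adjusted over the list alone, 4, -0.15, 3.07e-05, and 0.0088 with an estimated correlation) and mitochondrially encoded mRNAs in 2 of 13 (adjusted over the list alone, 7, -0.44, 1.07e-06, and adjusted p = 0.11 with an estimated correlation).

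Clock genes were higher in the libraries labelled OE_AUF than in sh_AUF in 3 of 15 cases and lower in 1 (adjusted over the list alone, 6 and 1; median 0.2, adjusted p = 0.00127; 0.034 with an estimated correlation, lost at 0.087 without OE_NC replicate 3), and mRNA decay genes in 1 of 47 (0.11, 0.00404; 0.022 with an estimated correlation). Long noncoding RNAs (2 higher, median 0.1, adjusted p = 0.025, and adjusted p = 0.33 with an estimated correlation) lost their call without sh_AUF replicate 1 (0.0512) or 3 (0.0547), and histones (0 called, -0.26, 0.0267, and adjusted p = 0.54 with an estimated correlation) without OE_AUF replicate 2 (0.136) or sh_AUF replicate 1 (0.0996) or 2 (0.0602). Ribosomal proteins and oxidative phosphorylation genes passed downward without OE_NC replicate 3 (0.00294 and 0.00254), but not with an estimated correlation as well (adjusted p = 0.85 and 0.75).

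In this direct comparison 419 genes were called, 246 higher and 173 lower, and 6520 did not overlap (46.8%, against 10% by chance). The share called higher was 58.7%, against 47.4% by recovered reads. The count was 5017 without OE_NC replicate 3, 267 and 279 without sh_NC replicates 1 and 2, 151, 149 and 170 without sh_AUF replicates 1, 2 and 3, and 147, 148 and 153 without those of OE_AUF.

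The control vectors were compared as background. No gene was called between OE_NC and sh_NC by limma (0 of 13942; 557 at an unadjusted p under 0.05, smallest adjusted p = 0.436), and 1937 did not overlap (13.9%, against 10% by chance). OE_NC replicate 3 stood apart from the other 5 control libraries. The median chi-square per gene between it and them was 16.4 to 17.8, against 0.705 to 0.824 between sh_NC and OE_NC replicates 1 and 2, and 0.455 from counting alone. It held 7750 FPKM of TMSB10, an actin-binding peptide gene, against 2640 in the other control libraries, and 1940 of the metallothionein MT2A against 662. Its ribosomal proteins lay a median of 1.1 log2 units and its oxidative phosphorylation genes 0.92 above those libraries, and long genes lay lower. TMSB10 and MT2A were chosen after their values were seen. Without it, 10766 genes were called in sh_AUF, including the 7758, and 10246 in OE_AUF, 7069 of them shared with the 7175.

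Libraries with AUF1 vectors differed from controls in composition. Mitochondrial ribosomal RNA took 1.08% ± 0.077 of reads in sh_AUF and 1.19% ± 0.052 in OE_AUF, against 0.355% ± 0.003 in sh_NC and 0.376% ± 0.039 in OE_NC (SD, n = 3). Long intergenic noncoding RNAs took 0.771% and 0.777%, against 0.37% and 0.357%. By biotype, a grouping chosen after the data were seen, 196 of 432 such genes were called higher and 67 lower in sh_AUF (camera adjusted p = 0.00053, and 0.37 with an estimated correlation). In OE_AUF these counts were 133 and 90, and the group did not pass (0.15, and 0.79 with an estimated correlation). Of 11091 protein-coding genes, 2728 were higher and 3785 lower in sh_AUF, and 2668 and 3368 in OE_AUF. Longer genes lay lower in all AUF1-vector libraries, with Spearman correlations of deviation and gene length of -0.267 to -0.215 in sh_AUF and -0.17 to -0.163 in OE_AUF, against -0.048 to 0.114 in 5 controls and -0.409 in OE_NC replicate 3. Markers of other cell types were mostly below the filter. Of 5 epithelial markers tested, 3 were higher in sh_AUF (median 0.64, adjusted p = 0.129) and 2 in OE_AUF (0.31, 0.405). Lists with fewer than 5 tested members had no list test. Keratinocyte markers had 0 of 1 called in either comparison, melanocyte markers 1 of 2 higher in each, leukocyte markers 1 of 1 higher in each, smooth muscle and pericyte markers 2 of 4 higher and 1 lower in each, and endothelial markers 1 of 2 lower in sh_AUF and 1 of 2 higher in OE_AUF.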

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

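Chosen after the results had been seen were the tests on HNRNPD and on the alike changes, those of gene length and of the AUF1-vector label for OE_NC replicate 3, the splits of the direct comparison, the regroupings, the marker counts at other scales, and the list tests without OE_NC replicate 3. Groups of 3 libraries are too small for a test of single outlying values.

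The lower HNRNPD in the libraries labelled OE_AUF (log2 difference -0.57) goes against their label. An exchange of the sh_AUF and OE_AUF labels would place HNRNPD above sh_NC in the libraries labelled sh_AUF, if overexpression raised the counted HNRNPD. There the sh_AUF difference was -0.369. If overexpression did not raise the count, exchanged labels could also give lower HNRNPD in both groups. The exchange thus stays open. The authors' scaling, or a gene length trend, would need the difference to vanish, but its highest value over 3 other scalings and the length adjustment was -0.334. Without OE_NC replicate 3 it was -0.477, which argues against that library as the cause. Reads of a vector cDNA that the counting missed, repression of the endogenous gene by its own protein and vectors that did not raise AUF1 remain open and were not tested.

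Changes of sh_AUF and OE_AUF were alike across genes. A gene length trend does not account for this, since the correlation was 0.832 after length adjustment, nor does OE_NC replicate 3, without which it was 0.908. A difference in preparation between the AUF1-vector and the control libraries stays open. The sh_NC libraries and OE_NC replicates 1 and 2 differed from each other by a median chi-square of at most 0.824, within the range of replicates. That can hold with or without a preparation difference, so it decides nothing. A preparation difference would follow the groups, so it cannot be told apart from a shared response to lower HNRNPD, or to both AUF1 vectors, which was not tested.

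OE_NC replicate 3 lay apart from the other control libraries. A gene length trend took 22.5% of the variance of its deviation, too little for the whole. An AUF1-vector library under a control label is argued against by the position of OE_NC replicate 3 over 930 genes. Both vectors changed these genes at least 2 times the same way, as found without this library. Its median position between the other controls (0) and the AUF1-vector libraries (1) was 0.254. The upper quartile was 0.523, against a lowest lower quartile of 0.904 in the AUF1-vector libraries. A first test, the slope over all genes (0.336), fell between its bounds and could not tell. It was replaced after it was seen. What moved this library part of the way was not tested. Cells of another type stay open: the condition set beforehand, 3 markers of 1 list at least 2 times above the other control libraries, was met by the epithelial KRT18 (182 against 75.7 FPKM), KRT7 and KRT8, but by 2 markers after scaling by recovered reads and 0 under TPM, as this library's FPKM sum was 415872.9 against 290293.9 or less in the other controls. A further condition, that a raised marker be below FPKM 1 in the other controls, was added after these values were seen, because 0 of the 3 were, 6 of the list's 10 members stayed below 1 in that library (highest 0.62), and ribosomal proteins were raised as much (1.1); by the first condition alone, at the deposited scale, the test would have favoured such cells.

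Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split gave 10581 calls for sh_AUF, 4729 for OE_AUF and 4035 for the direct comparison, each in 1 of 10 splits, with 0 as the highest other; the control comparison gave 0 in all 10. Of 100 regroupings for the difference between the vector responses, 4 gave as many calls as the real 100, the real one included, and the highest other gave 132. Regrouped libraries mix the groups, so real differences between groups widen the spread, as in the splits with 0 calls. The share under 0.05 is thus partly built in, and no conclusion is drawn from it.

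The responses to both vectors differed by test for 27 named genes, 18 with a higher and 9 with a lower change in the libraries labelled OE_AUF. The log2 differences were 1.372 for SLC7A5, 1.288 for ASNS, 1.236 for PSAT1, 1.236 for ALDH1L2, 1.189 for OAS2, 1.013 for DDX58, 0.952 for AARS, 0.935 for OAS1, 0.905 for STC2, 0.878 for TRIB3 and 0.816 for CHAC1. They were 0.768 for IFI44, 0.712 for TXNIP, 0.691 for PTX3, 0.677 for DDIT4, 0.631 for IL1B, 0.567 for MX1 and 0.557 for IFIT3. Lower were CTGF at -0.563, PPP1R10 at -0.577, SPARC at -0.588, COL1A2 at -0.592, DKK1 at -0.805, HTRA1 at -0.913, CAVIN1 at -0.945, MEST at -1.202 and ADM at -1.304. Among those named for their size in this comparison, ADM, CAVIN1, HTRA1, OAS2 and DDX58 lost the call without any of several single libraries, with adjusted p up to 0.057, 0.0831, 0.151, 0.057 and 0.123 among them.

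The median differences of 13 lists passed camera's test at the preset correlation. Upward were ATF4 and amino acid response at 0.686, interferon-stimulated genes at 0.443, inflammatory genes at 0.307 and the clock at 0.204. Downward were collagens at -0.036, myofibroblast genes at -0.161, cholesterol synthesis at -0.217, glycolysis at -0.244, proteasome subunits at -0.296, fibroblast identity at -0.386, oxidative phosphorylation at -0.434, ribosomal proteins at -0.439 and mitochondrially encoded mRNAs at -0.605. With an estimated correlation the clock and all 9 downward lists lost the call, with adjusted p of 0.064 to 0.76. With OE_NC replicate 3 also left out, cholesterol synthesis, glycolysis and fibroblast identity (0.011 each) and myofibroblast genes (0.036) passed, as did mRNA decay genes (0.032), while the clock (0.11) and the other 5 downward lists did not. Under TPM the medians of collagens, myofibroblast genes, cholesterol synthesis and glycolysis were above 0, though below that of all genes. Without OE_NC replicate 3 medians were -0.08 for ribosomal proteins, -0.1 for oxidative phosphorylation, -0.03 for proteasome subunits, -0.16 for collagens, -0.21 for fibroblast identity, -0.14 for cholesterol synthesis and -0.16 for glycolysis. The call of proteasome subunits ended without that library (0.146), and those of collagens and myofibroblast genes without OE_NC replicate 1 (0.33 and 0.158) or 2 (0.411 and 0.2); each of the 3 also ended without others, at 0.0507 to 0.0835.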

How the results depend on the processing

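Scaling by recovered reads, length adjustment, the direct comparison, the count of same-direction calls and the lists without OE_NC replicate 3 were chosen after the data were seen. HNRNPD stayed below its controls in all settings, past the threshold except for sh_AUF with length adjustment (-0.229, adjusted p = 0.0956; range 2.79e-07 to 0.0956). Over 219 results of named genes, 4623 values kept direction and side of the threshold, 369 lost the call, 4 gained it and 2 reversed: B4GAT1 in OE_AUF was 0.001 under TPM and 0.005 by recovered reads. The causes of the changes below were not tested, except where fewer genes or libraries entered. OE_NC replicate 3 enters the sh_AUF and direct comparisons only through the spread shared by all 12 libraries.

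Without a filter, 53 genes were called for the difference between responses, 6 for the controls and 277 for the direct comparison. With mean FPKM of at least 5, where fewer genes were tested, 4033 were called in sh_AUF, 3825 in OE_AUF and 2853 the same way in both. TPM gave 21 opposite calls. The 6 libraries alone gave 10581 for sh_AUF, 4729 for OE_AUF and 4035 for the direct comparison. Protein-coding genes alone gave 152 for the difference; length adjustment gave 219, and 734 directly. Camera with an estimated correlation called 0 lists in sh_AUF and 2 in OE_AUF, against 13 each; with OE_NC replicate 3 also left out it called 1, 3 and, directly, 8.

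Leaving out each library in turn gave 6505 to 10766 calls for sh_AUF, 6074 to 10246 for OE_AUF, 19 to 2738 for the difference, 0 to 0 for the controls, 147 to 5017 directly, 16 to 168 opposite and 4797 to 8940 alike. HNRNPD ranged from -0.393 to -0.352 in sh_AUF and -0.623 to -0.477 in OE_AUF, r from 0.718 to 0.908, and called lists from 11 to 15, 12 to 13 and, directly, 11 to 15. Without OE_NC replicate 3 the counts of genes, other than the controls' 0, and r were highest, while called lists were 15 for sh_AUF and directly but 12, the lowest, for OE_AUF.

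Numbers did not pair the libraries: correlations of same-numbered deviations were -0.015, 0.092 and 0 for sh and -0.032, 0.026 and -0.048 for OE, and 2 of 6 were best with their own number. With replicate as a block, 21 genes were called for the difference and 181 directly, 7375 in sh_AUF and 6787 in OE_AUF. Depth of 18062172 to 25673595 reads limits genes near 0.114 to 0.186 FPKM; the spread among 3 libraries limits the rest.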

Other observations

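All gene groups in this part, 42 per comparison of which 12 were picked by hand and the rest by biotype or transcription factor family, were chosen after the data were seen, as was the direct test of AU-rich elements; the tests of AU-rich elements in sh_AUF and OE_AUF were set beforehand. MHC class II genes, which present antigen to helper T cells, rose in 10 of 10 cases in sh_AUF (median log2 change 1.52, camera adjusted p = 6.9e-07; adjusted p = 0.13 with an estimated correlation) and were higher in 9 of 10 in the libraries labelled OE_AUF (1.25, 5.1e-06; adjusted p = 0.14 with an estimated correlation). CD74, the invariant chain, went from 0.8 to 5.35 FPKM in sh_AUF and HLA-DPA1 from 4.23 to 12.1. Arrestin-domain genes rose in 6 of 7 cases in sh_AUF (median 1.1, camera adjusted p = 0.00053, and 0.04 with an estimated correlation). They rose in 5 of 7 in OE_AUF (0.72, 0.0031, and adjusted p = 0.06 with an estimated correlation). ARRDC4 went from 0.834 to 5.17 FPKM in sh_AUF. This group holds TXNIP and ARRDC3, and MHC class II holds HLA-DRA and HLA-DRB1, all named above among the largest increases. The tests of both groups thus partly repeat those results. Nucleolar genes of ribosome biogenesis fell in 28 of 29 cases in sh_AUF (-0.98, adjusted p = 2.6e-09; 0.026 with an estimated correlation) and were lower in 26 in OE_AUF (-0.84, 7.5e-09; 0.037 with an estimated correlation), among them nucleolin (NCL), from 165 to 73.6 FPKM in sh_AUF. All 8 subunits of the cytosolic chaperonin were lower in both (-0.89 and -0.87, adjusted p = 2e-04 each; adjusted p = 0.25 and 0.27 with an estimated correlation).

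Between the AUF1-vector groups, some genes that supply amino acids or charge cytosolic tRNAs were higher in the libraries labelled OE_AUF. The cytosolic synthetases, the serine and one-carbon enzymes and the amino acid transporters share members with the ATF4 and amino acid response list. Shared members include AARS, PSAT1, MTHFD2 and SLC7A5, so the tests of these groups partly repeat that list's result. Cytosolic aminoacyl-tRNA synthetases were higher in 12 of 20 cases and lower in 0 (median 0.59, adjusted p = 3.2e-16; 0.0088 with an estimated correlation), with AARS at 175 against 88.6 FPKM. Mitochondrial aminoacyl-tRNA synthetases, 16 in number, did not pass (median 0.03, adjusted p = 0.77). Serine and one-carbon enzymes were higher in 5 of 11 cases (median 0.56, camera adjusted p = 1.3e-09, and 0.0054 with an estimated correlation), with MTHFD2 at 67.5 against 37.6. Amino acid transporters were higher in 5 of 13 (0.59, 2.1e-08, and 0.018 with an estimated correlation), with SLC6A9 at 7.39 against 4.05. Without OE_NC replicate 3, 16 cytosolic synthetases, 9 of these enzymes and 9 transporters were higher, and 1 transporter was lower. Against their own controls, the cytosolic synthetases were lower in 14 and higher in 2 of 20 cases in sh_AUF (adjusted p = 0.024, and adjusted p = 0.3 with an estimated correlation) and went both ways in OE_AUF (7 higher, 6 lower, 0.41). The mitochondrial synthetases were lower in 10 and higher in 0 of 16 cases in sh_AUF (median -0.37, camera adjusted p = 0.012, and 0.091 with an estimated correlation). In OE_AUF 11 were lower and 1 higher (-0.41, 0.021, and 0.11 with an estimated correlation). The transporters were lower in 10 and higher in 1 of 13 in sh_AUF (0.012, and adjusted p = 0.2 with an estimated correlation) and went both ways in OE_AUF (5 and 4, 0.64), as did the serine and one-carbon enzymes in both (2 and 5, 0.31, and 5 and 4, 0.29).

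A hypothesis was that mRNAs with an AU-rich nonamer in the 3' UTR, a site AUF1 can bind, change with lower HNRNPD. Over 10977 protein-coding genes with an annotated 3' UTR (99% of those tested), 2415 had the nonamer. Their unadjusted median change was -0.184 in sh_AUF, against -0.049 without the nonamer, and -0.018 against -0.093 in OE_AUF (-0.107 against -0.052 without OE_NC replicate 3). Adjusted for UTR length, AU content, expression and gene length, they differed from the others by 0.001 log2 units in sh_AUF (95% interval -0.026 to 0.028, permutation p = 1), which argues against a shift of 0.05 or more beyond what these covariates take up. In OE_AUF the difference was 0.03 (0.004 to 0.057, permutation p = 0.05), and 0.02 (-0.007 to 0.047) without OE_NC replicate 3, which leaves that question open. Directly, the libraries labelled OE_AUF had them 0.021 higher than sh_AUF (0.012 to 0.03, permutation p = 7e-05). That interval lies below the shift of 0.05 named above. HNRNPD was not called between these groups (log2 difference -0.12, limma adjusted p = 0.519), so the direct comparison does not test the hypothesis. Genes are not independent replicates, so these p-values describe genes in these libraries.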
